A study of Mus musculus with 2 samples.

How the data were processed

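H3K36me3 ChIP-seq was measured in forebrain of mouse embryos (strain B6NCrl, embryonic day 15.5, males and females pooled) in 1 group of 2 biological replicates. Per the labels, replicate 1 was a pool of 78 embryos with 3 technical replicates and replicate 2 a pool of 62 embryos with 2 technical replicates. The replicate numbers come from the labels. The labels name a possible control experiment, which was not analysed here.

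The authors deposited 4 peak lists in narrowPeak format on the mouse assembly mm10, 1 for each replicate, a joint list made from both replicates, and a replicated list. Per the file headers of the accompanying text records, the replicated list was derived from the joint list and both replicate lists. The list of replicate 1 was made with 2 further source files besides its own alignment and that of replicate 2 with 1. The aligner, the peak caller, its background model and its threshold are not given in the sources used here. Each peak has a position, a signal value that was read as the authors' fold over background, since it exceeds 1 in every peak, and a −log10 p and a −log10 q as deposited. The lowest deposited −log10 p was between 2.00 and 2.03 in all 4 lists, and the lowest −log10 q was between 0.424 and 0.630, so weak peaks are included. The lists hold no read counts, and the depth of each library is unknown. A library with more reads, or with more control data, gives more and wider peaks, which moves every percent covered given here. The fold, p and q values were used only to rank, filter or describe peaks within a list, except where the closing section compares paired peaks.

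Gene models came from GENCODE release M21, which is on GRCm38, the same assembly as mm10. Peak positions were used as deposited, and are printed 1-based. Chromosome lengths and the assembled range of each chromosome were read from the reference sequence. Peaks on chromosomes 1 to 19 and X entered the gene results, and those on chromosome Y and on unplaced scaffolds were left out and are described in the closing section. Overlapping peaks within a list were merged. The percent of the span covered by peaks was computed per replicate for 20951 protein-coding genes of at least 1 kb, and averaged over the replicates. A gene was marked at 10% or more in both replicates. Gene spans run from the first to the last annotated base over all transcripts, and exons are the union over protein-coding transcripts. All other bases of the span were counted as intron. Genes were compared from their midpoint in those of at least 10 kb, and exons with introns in those with at least 1 kb of intron.

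Overlap of peaks, the genic share and the number of marked genes were set against 100 circular shifts of the peaks within the assembled part of each chromosome (one-sided, smallest p 0.0099). The comparisons along genes and of exons with introns were averaged per chromosome and tested by flipping signs over the 20 chromosomes (two-sided, 100000 resamples, smallest p 1e-05). Gene lists were compared with 10000 random lists in which each member was replaced by 1 of the 100 genes nearest in length, two-sided (smallest p 2e-04), with Benjamini-Hochberg adjustment over the 30 lists and families. Differences between lists were tested on each gene's percentile among the 200 genes nearest in length, by permuting list membership (100000 resamples, two-sided, adjusted over 5 contrasts). The list test was tested on simulated data for lists of 20 among the 20951 genes. Of 100 simulated lists it called 5 with no shift, 23 when members were raised by 5 percentage points, 57 at 10 points and 100 at 20 points. These calls used an unadjusted p under 0.05 and fewer random lists, and lowered members were not simulated. The rates are therefore not those of the adjusted calls given below. Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9. The replicates form a single group, so there was no comparison between groups to pair, and no outlier test applies to 2 samples.

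The lists covered radial glia, the cell cycle, intermediate progenitors, cortical excitatory neurons, GABAergic neurons, pan-neuronal genes, axon guidance, mature synapses, oligodendrocytes, astrocytes, microglia, endothelium, erythroid cells, meningeal fibroblasts, choroid plexus, hepatocytes, muscle, germline, the H3K36 methylation machinery, imprinted genes and patterning factors of hindbrain and spinal cord. The 9 families were ribosomal proteins, proteasome, complex I, olfactory receptors, vomeronasal receptors, keratins, Hox genes, Zfp genes and clustered protocadherins. Named genes followed a rule: the 10 genes of at least 20 kb with the highest mean coverage, up to 3 highest and 2 lowest members of each list (ties to the longer gene), 2 highest of each family, the 5 genes of at least 20 kb with the largest difference in each direction between replicates, the genes lying mostly inside the 5 longest domains, and the genes with the 5 highest peaks. Some of these are not printed. Other genes are said to be chosen after their values were seen.

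These choices were made before the data were examined, as were the alternatives. They were peaks with −log10 q of at least 2, an equal number of top peaks in both replicates, leaving out each replicate, other overlap, coverage and joining thresholds, promoters of 2 kb, all annotated genes, genes of at least 50 kb, exons without first exons, the replicated list in place of the replicates, no length matching, and only genes that overlap no other. Leaving out last exons as well was added after the data had been seen.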

Results

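The series mapped H3K36me3, a trimethylation of histone H3 laid down over gene bodies as RNA polymerase II transcribes them, in the forebrain of mouse embryos at embryonic day 15.5. The embryos were of strain B6NCrl, and males and females were pooled. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on 2 biological replicates of 1 group, a pool of 78 embryos for replicate 1 and a pool of 62 embryos for replicate 2. The labels give no second condition, so the questions the design allows are where the mark lay, which kinds of gene carried it, and how far the 2 pools shared it. The number of reads behind each peak list is unknown, so no counting error can be given. Errors are the SD between the 2 replicates. Positions are on mm10.

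Peaks of H3K36me3 covered 3.80% of the assembled sequence of chromosomes 1 to 19 and X in replicate 1 and 2.53% in replicate 2. Replicate 1 had 173139 peaks over 97.8 Mb, and replicate 2 had 148060 peaks over 65.1 Mb, so the covered length differed 1.5-fold. The mean was 81.5 ± 23.1 Mb (SD, n = 2). The median peak was 347 bp wide in replicate 1 and 307 bp in replicate 2. The authors also deposited a joint list of 159874 peaks made from both replicates, and a replicated list of 109109 peaks covering 89.7 Mb.

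The same places were marked in both pools far beyond chance placement. Peaks of the 2 replicates shared 53.0 Mb, which was 54.2% of the covered bases of replicate 1 and 81.4% of those of replicate 2. Of the replicate 2 peaks, 77.2% had at least 50% of their length under replicate 1 peaks, where circularly shifted lists gave a mean of 4.25% and at most 7.71%. In the other direction 42.9% of the replicate 1 peaks lay under replicate 2 peaks, against a mean of 2.75% and at most 3.97% after shifting. This share was 20.8% when 80% of the peak had to overlap. Both shares had a one-sided permutation p = 0.0099, the smallest that 100 shifts can give. Every peak of the replicated list was also a peak of the joint list. At the same overlap, 93.9% of the replicated peaks lay under replicate 1 and 67.5% under replicate 2, and 1.54% lay under neither.

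H3K36me3 lay almost wholly within protein-coding genes and left their promoters out. Gene bodies held 94.6 ± 0.34% of the covered bases (SD, n = 2), although they make up 40.3% of the assembled sequence. Shifted lists placed 42.1% there on average and 44.6% at most (one-sided permutation p = 0.0099, the smallest possible). Promoters, taken as 1 kb either side of a transcription start, held 0.404 ± 0.0031% of the covered bases and 1.59% of the genome. Exons outside promoters held 19.2 ± 0.96% of the covered bases against 2.60% of the genome, and introns 75.1 ± 0.61% against 36.8%. The remaining 5.32 ± 0.34% lay outside protein-coding genes and promoters, which make up 59.0% of the genome.

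The mark grew along the gene. In the 4668 marked genes of at least 10 kb, the gene span was cut into 10 equal bins. From the 5′ end, bin 1 was 4.34 ± 1.4% covered, bin 5 was 41.0 ± 9.3%, bin 9 was 55.7 ± 11.0% and bin 10 was 51.9 ± 10.8% (SD, n = 2). The kilobase before the start was 1.02 ± 0.25% covered and the kilobase after the end 37.9 ± 9.7%. From the midpoint to the 3′ end, 51.0 ± 10.5% of the bases were covered, against 25.6 ± 6.4% from the start to the midpoint. The 3′ part was higher in 88.7% of these genes and in 20 of 20 chromosomes, by a mean of 24.9 percentage points with an SD of 3.26 over chromosomes (two-sided sign-flip permutation p = 1e-05, the smallest that the resamples can give). Exons were also covered more than introns. In 5952 marked genes 51.5 ± 9.6% of exonic and 35.1 ± 8.0% of intronic bases were covered, a difference of 16.4 percentage points with an SD of 1.29 over chromosomes, in the same direction in 20 of 20 (permutation p = 1e-05). Exons and introns were not matched for position along the gene, so this difference was not separated from the rise towards the 3′ end.

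**Figure D1:**
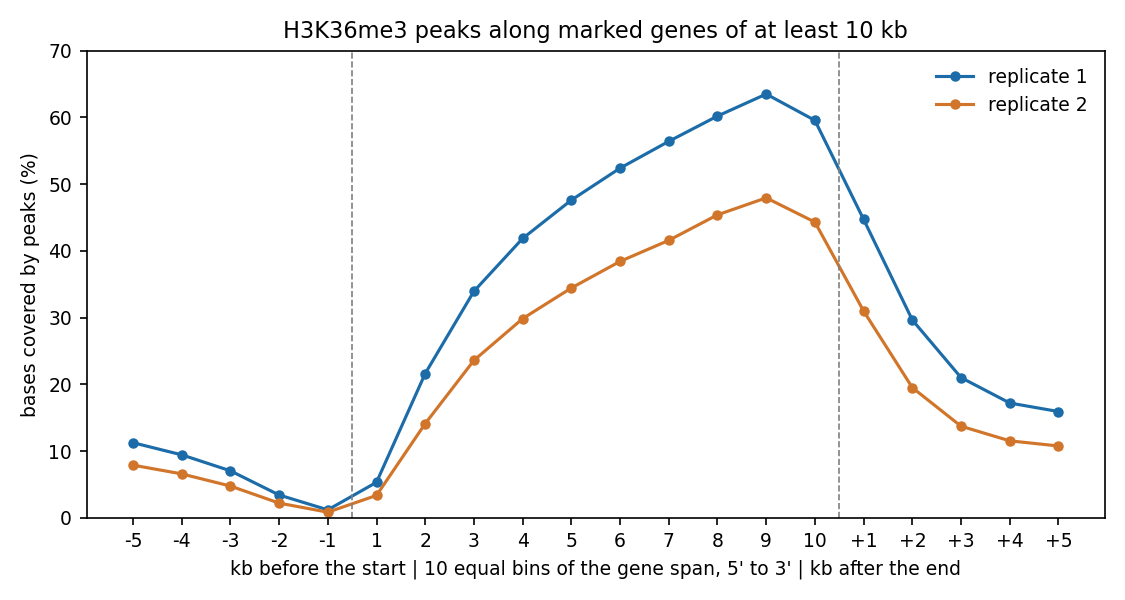
Percent of bases covered by H3K36me3 peaks (vertical axis) in marked genes of at least 10 kb, for the 5 kb before the start, 10 equal bins of the gene span and the 5 kb after the end (horizontal axis). The points are the 2 replicates, and in both the coverage climbs to bin 9, at 63.5% in replicate 1 and 48.0% in replicate 2.

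A gene was called marked when at least 10% of its span was covered in both replicates. Of the 20951 protein-coding genes measured, 6074 (29.0%) were marked, where shifted lists gave 1683 on average and 1841 at most (one-sided permutation p = 0.0099, the smallest possible). A further 9814 genes (46.8%) held no peak base in either replicate. The marked share was highest in genes of 20 to 50 kb, at 41.2% of 5035 genes. It was 14.2% in genes of 1 to 5 kb and 2.71% in genes of 200 kb or more, although 76.6% of the latter held some peak base. The number fell to 3684 when 25% of the span had to be covered.

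The 10 most fully covered genes of at least 20 kb had between 82.4% and 86.0% of their span under peaks. Sf3b3, a subunit of the SF3b complex of the U2 spliceosomal particle, was first at 86.0 ± 4.1% (SD, n = 2; chromosome 8, 110810239 to 110846787). Prpf8, the core protein of the spliceosome, was 85.3 ± 4.4% covered (chromosome 11, 75486816 to 75509449), and Snrnp200, its RNA helicase partner, 85.3 ± 4.2% (chromosome 2, 127208386 to 127240451). Sf3a1 had 83.1 ± 6.0%, the splicing regulator Rbm5 85.5 ± 4.3% and the RNA-binding protein gene Hnrnpul1 82.5 ± 6.5%. The other genes among the top 10 were Kpnb1, which encodes importin beta, at 85.7 ± 4.4%, Prr12 at 82.8 ± 5.5%, Trrap, a scaffold of histone acetyltransferase complexes, at 82.7 ± 9.5%, and Ddb1, a DNA damage and ubiquitin ligase component, at 82.4 ± 8.9%. Sf3b3 and Ddb1 each overlap another protein-coding gene. ChIP-seq peaks have no strand, so coverage of overlapping genes cannot be assigned to either.

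With replicated peaks joined within 3 kb, the longest domains of the mark ran over the bodies of large genes such as Vps13d, Mtor and Wdfy3. Joining replicated peaks within 3 kb gave 19027 domains with a median of 2.91 kb, of which 216 were 50 kb or longer and 14 were 100 kb or longer. The longest, 139.0 kb on chromosome 4 (145051511 to 145190506), lay within Vps13d, a lipid transfer protein gene. The next, 130.7 kb on chromosome 4 (148452099 to 148582795), spanned Mtor, the growth-controlling kinase, and Exosc10, a catalytic subunit of the RNA exosome. Mtor was 65.4 ± 12.6% covered and Exosc10 80.6 ± 6.5%, and Angptl7, which lies inside Mtor, had 25.8 ± 8.0%. The others lay over Wdfy3, a selective autophagy adaptor gene (129.5 kb, chromosome 5), over Hectd4 and Trafd1 (128.2 kb, chromosome 5), and over Mdn1, an ATPase gene of ribosome assembly (114.4 kb, chromosome 4). The number of domains depended on the joining distance, with 34047 at 1 kb and 10534 at 10 kb. At those distances 35 and 897 domains reached 50 kb, and the longest was not that in Vps13d. It was 104.7 kb on chromosome 5 (121277463 to 121382149), inside the domain over Hectd4 and Trafd1, at 1 kb, and 232.2 kb on chromosome 12 (75880307 to 76112458) at 10 kb.

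The highest peaks belonged to zinc finger genes. The 5 replicated peaks with the highest fold, which is the authors' own value per peak, lay in Zfp157, Zfp37, Zfp68 (which held a pair) and Zfp146. Their folds were 12.9 in Zfp157 (chromosome 5, 138454340 to 138459825), 12.9 in Zfp37 (chromosome 4, 62191097 to 62196195), 12.7 and 12.5 in Zfp68, and 12.3 in Zfp146 (chromosome 7, 30160615 to 30164369). The peak in Zfp146 covered all of the gene's last exon, that in Zfp157 82.0%, that in Zfp37 50.6%, and the pair in Zfp68 80.6% and 0%. Proteins of this family carry arrays of C2H2 zinc fingers, and many repress transposable elements. Reads shared between near-identical members of the family can affect the coverage of single genes.

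Lists of cell type markers, pathways and gene families had been fixed before the data were examined. Of 30 such lists, 8 were covered above random lists of the same gene lengths and 16 below, and 6 did not pass the test (two-sided permutation tests with Benjamini-Hochberg adjustment over the 30, adjusted p under 0.05). The smallest p that the 10000 random lists can give is 2e-04, which becomes 5e-04 after adjustment. These tests describe these libraries, since genes are not independent replicates. Forebrain is a mixture of cell types, so low coverage of a marker cannot tell absence of the mark from few cells that carry it.

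Families of cell maintenance genes were covered above random lists. Cytosolic ribosomal protein genes averaged 34.7 ± 6.0% covered against 7.43% in random lists, and 61 of 81 were marked (adjusted permutation p = 5e-04). Rps3 reached 73.9 ± 6.4% and Rpl5, which overlaps another protein-coding gene, 70.6 ± 2.9%. Proteasome subunit genes averaged 38.6 ± 6.3% against 12.9%, with 31 of 39 marked (adjusted permutation p = 5e-04), led by the ATPase subunit genes Psmc1 at 74.5 ± 5.4% and Psmc6 at 69.8 ± 6.4%. Genes of respiratory complex I averaged 27.8 ± 8.6% against 12.1%, with 26 of 36 marked (adjusted permutation p = 5e-04), led by Ndufa10 at 64.8 ± 12% and Ndufa9 at 63.9 ± 12.5%.

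Genes that write, erase or read H3K36 methylation were themselves highly covered, at 39.0 ± 6.6% against 12.04% in random lists, with 14 of 18 marked (adjusted permutation p = 5e-04). The demethylase gene Kdm4a had 80.9 ± 8.0% (chromosome 4, 118136957 to 118180043), Brpf1, which encodes a PWWP-domain reader, 70.1 ± 3.3%, and Supt6, a transcription elongation factor gene that overlaps another protein-coding gene, 68.8 ± 5.1%. The lowest members were the DNA methyltransferase gene Dnmt3b at 2.91 ± 2.7% and Setd3, whose product methylates actin, at 10.7 ± 5.5%. The 391 genes named Zfp averaged 27.3 ± 5.3% against 15.2%, and 245 were marked (adjusted permutation p = 5e-04). Zfp606 had 87.0 ± 0.50% and Zfp110 86.5 ± 1.2%. Clustered protocadherin genes averaged 14.05 ± 5.0% against 7.55%, with 20 of 56 marked (adjusted permutation p = 0.00263), and Pcdhga3 had 41.6 ± 12.4% and Pcdhga4 41.3 ± 11.3%. Their genes overlap one another and share constant exons, so the members are not separate measurements, and without length matching the call was lost (adjusted permutation p = 0.509).

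Cell cycle genes and pan-neuronal genes were covered above random lists, close to the threshold. Cell cycle and DNA replication genes averaged 26.2 ± 6.4% against 15.6%, and 16 of 20 were marked (adjusted permutation p = 0.0466). The replicative helicase genes Mcm7, Mcm4 and Mcm6 led them at 61.7 ± 7.1%, 61.0 ± 6.8% and 43.6 ± 11.0%, and Ccnb1 (4.43 ± 3.0%) and Rrm2 (5.30 ± 1.2%) were lowest. Of these Mcm7 overlaps another protein-coding gene. Pan-neuronal genes averaged 16.0 ± 3.9% against 8.76%, with 8 of 21 marked and none without a peak base (adjusted permutation p = 0.0496). Crmp1, a semaphorin signalling mediator, had 48.2 ± 6.3%, Stmn1, a microtubule destabiliser, 39.8 ± 5.4% and Ina, a neuronal intermediate filament gene, 37.0 ± 8.9%, and of these Crmp1 and Ina each overlap another protein-coding gene. The very long genes Rbfox3 (0.119 ± 0.098%) and Nrxn1 (0.259 ± 0.088%) were lowest. With replicate 2 alone the cell cycle list had an adjusted permutation p of 0.0605 and the pan-neuronal list 0.0600, and each was also lost under several other settings.

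Markers of the forebrain's own stages and neuron classes did not stand above random lists. Radial glia genes averaged 6.72 ± 1.9% against 10.2% (adjusted permutation p = 0.451). Vim, the radial glial intermediate filament, had 36.5 ± 10.2%, the receptor phosphatase gene Ptprz1 15.6 ± 3.5% and Notch1 13.8 ± 6.8%, while Hopx and Emx2 held no peak base. Intermediate progenitor and proneural genes averaged 4.29 ± 0.87% against 10.7% (adjusted permutation p = 0.228). The Notch ligand gene Dll1 had 36.3 ± 1.8% and was the only marked member of 13, and Neurod4 and Dll3 held no peak base. Cortical excitatory neuron genes averaged 2.46 ± 1.4% against 6.84%, with none of 20 marked (adjusted permutation p = 0.128). Cux1, a transcription factor gene of upper-layer neurons, had 9.70 ± 3.4%, and Bcl11b, a regulator of deep-layer projection neurons, 4.88 ± 0.92%, while Tbr1 and Fezf2 held no peak base. Axon guidance genes averaged 4.88 ± 1.5% against 3.93% (adjusted permutation p = 0.598), with Plxna2 at 37.4 ± 7.3% and the adhesion gene Cntn2 at 25.3 ± 7.6% as the 2 marked members. Mature synapse and ion channel genes averaged 4.23 ± 2.4% against 8.38% (adjusted permutation p = 0.166), led by the postsynaptic scaffold gene Dlg4 at 26.2 ± 6.6%. Imprinted genes averaged 11.1 ± 3.6% against 11.3% (adjusted permutation p = 0.990). Nnat, which overlaps another protein-coding gene, had 60.8 ± 4.5%. Impact had 37.8 ± 10.5% and Igf2r 35.3 ± 11.7%, and Igf2 held no peak base. For the excitatory list the mean lay below the mean of random lists but within their central 95%, while its mean rank within genes of the same length was 60.0 on a scale of 0 to 100, and 4 of its 20 members held no peak base.

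**Figure D2:**
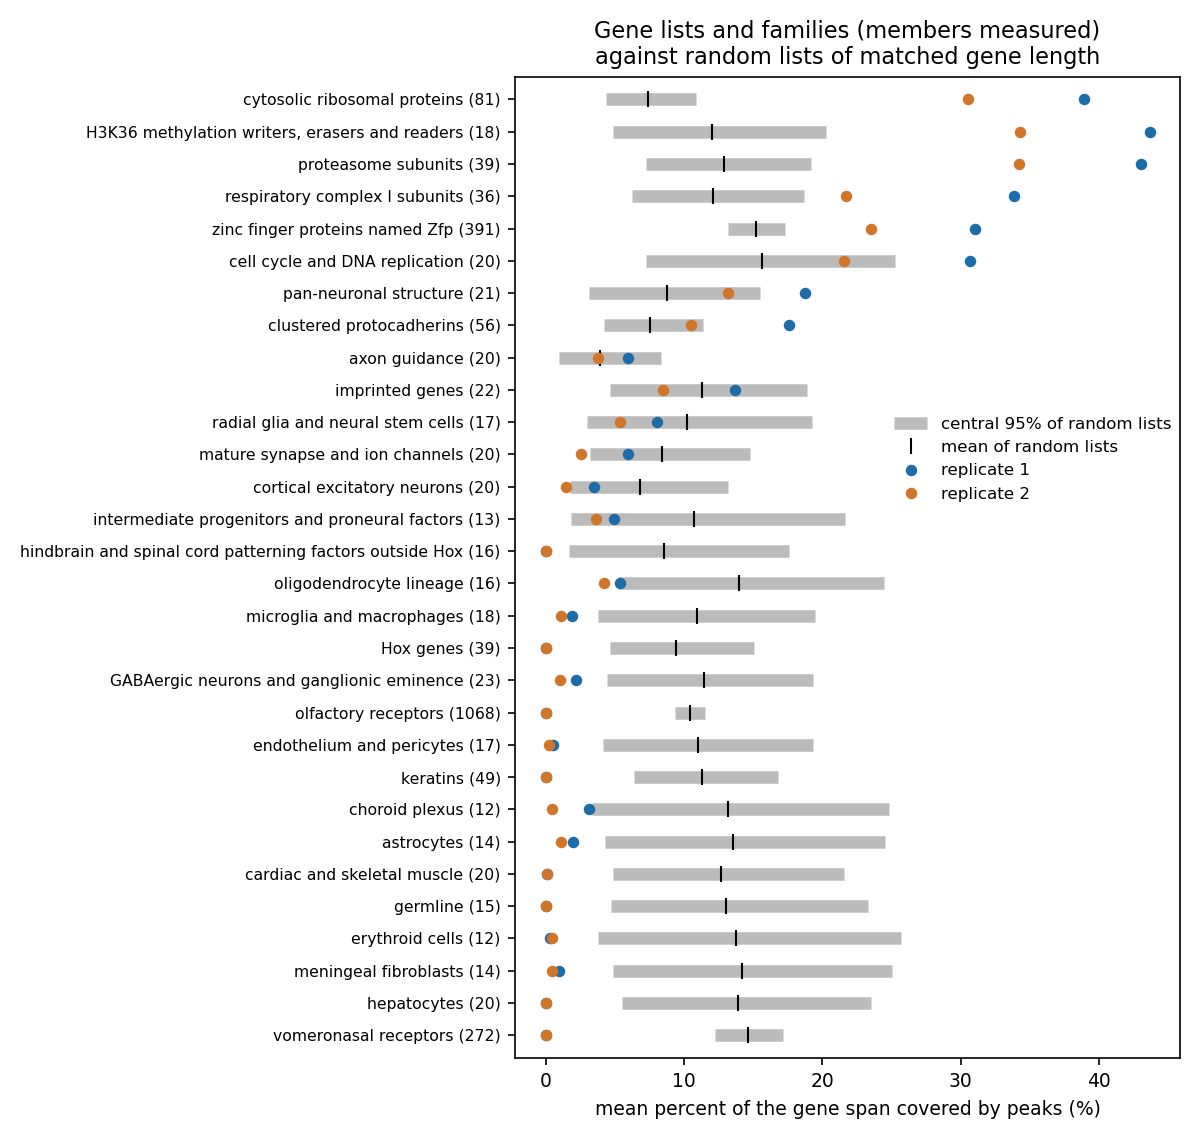
Mean percent of the gene span covered by peaks (horizontal axis) for 30 gene lists and families, with the number of members measured in brackets. Points are the 2 replicates, grey bars the central 95% of random lists of matched gene length and ticks their mean. Ribosomal protein genes lie at 38.9% and 30.5% in the 2 replicates against 7.43% in random lists, and Hox genes lie at 0.

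GABAergic markers were covered below random lists, at 1.60 ± 0.83% against 11.4%, with 1 of 23 marked (adjusted permutation p = 0.003). The exceptions were the genes for GABA synthesis, Gad2 at 18.3 ± 9.3% and Gad1 at 15.5 ± 8.1%. Gad2 is the member that was marked in both replicates, and Gad1 had 21.3% in replicate 1 and 9.80% in replicate 2. The transcription factor genes Maf and Lhx8 held no peak base, and 18 of the 23 members held none, against 4 of 20 excitatory genes. The excitatory list ranked above the GABAergic list within genes of the same length by 23.1 points (60.0 against 36.9, two-sided permutation, adjusted p = 0.00095 over 5 contrasts). On percent covered with no length adjustment this difference was 0.853 percentage points (adjusted permutation p = 0.644). Mature synapse genes ranked 18.9 points below pan-neuronal genes (55.5 against 74.4, adjusted permutation p = 0.00412). Intermediate progenitor genes ranked at 49.1 and radial glia genes at 55.0 (adjusted permutation p = 0.566), and oligodendrocyte genes at 33.6 and astrocyte genes at 35.1 (adjusted permutation p = 0.832), so neither difference passed the test.

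Markers of glia and of the other cell types of the tissue were covered below random lists. In a mixed tissue this cannot tell absence of the mark in those cells from few such cells. Astrocyte genes averaged 1.52 ± 0.60% (adjusted permutation p = 0.0075), and Aqp4 and Sparcl1 held no peak base. Microglia and macrophage genes averaged 1.53 ± 0.59%, with 14 of 18 members without a peak base (adjusted permutation p = 0.00663). Endothelial and pericyte genes averaged 0.381 ± 0.20%, with 14 of 17 at 0, among them Erg and the VEGF receptor gene Flt1 (adjusted permutation p = 0.000923). Erythroid genes averaged 0.405 ± 0.11% over 12 of 15 symbols measured (adjusted permutation p = 0.003), meningeal fibroblast genes 0.721 ± 0.39% (adjusted permutation p = 0.00171) and choroid plexus genes 1.81 ± 1.9% (adjusted permutation p = 0.022). Of the meningeal genes Fn1, which encodes fibronectin, had 9.80 ± 5.3%. Oligodendrocyte genes averaged 4.83 ± 0.83% against 14.0% (adjusted permutation p = 0.0497), a call that was lost with replicate 2 alone (adjusted permutation p = 0.0795) and under other settings. With only the 13 members that overlap no other gene, the oligodendrocyte list averaged 0.906% against 13.0% (adjusted permutation p = 0.0105), so the call held there. Of the oligodendrocyte genes Pdgfra and Ugt8a held no peak base. The highest members of several of these lists overlap another protein-coding gene, so their coverage cannot be assigned to them. These were Cnp at 65.5 ± 7.9%, the astrocyte marker Slc7a10 at 12.6 ± 1.0%, the microglial receptor gene Cx3cr1 at 12.8 ± 2.0% and the choroid plexus channel gene Kcnj13 at 21.5 ± 22.4%. Among members that overlap no other, Mog of the oligodendrocyte list had 10.9 ± 6.0%, Fcer1g of the microglia list 7.23 ± 8.0% and F3 of the astrocyte list 3.47 ± 4.9%.

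Genes of other organs and of other body regions held almost none of the mark. Hepatocyte genes averaged 0.0212 ± 0.030%, with 19 of 20 at 0, muscle genes 0.103 ± 0.0022%, with 16 of 20 at 0, and germline genes 0.0171 ± 0.024%, with 14 of 15 at 0 (adjusted permutation p = 5e-04 for each). Together these ranked 28.8 points below the neural lists within genes of the same length (adjusted permutation p = 5e-05). The neural lists pooled there were radial glia, intermediate progenitors, excitatory, GABAergic, pan-neuronal and axon guidance genes, without mature synapse genes. None of 39 Hox genes held a peak base in either replicate, nor did any of 16 other patterning factors of the hindbrain and spinal cord, such as Pax2 and Lmx1b (adjusted permutation p = 5e-04 and 0.002). A lack of peak bases was not particular to genes of other body regions. In the forebrain's own lists, 18 of 23 GABAergic and 4 of 20 excitatory members held none. No contrast of the Hox or patterning genes with those lists was run. All 49 keratin genes were at 0, as were 1067 of 1068 olfactory receptor genes and 269 of 272 vomeronasal receptor genes (adjusted permutation p = 5e-04 for each). The exception among the olfactory receptors was Olfr1489 at 1.66 ± 0.011%.

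Fewer genes were marked on the X chromosome than on any autosome, and peaks covered less of their span. Of 877 X-linked genes 57 were marked (6.50%), against a mean of 30.1 ± 3.76% (SD over 19 autosomes) and a lowest autosome, chromosome 14, at 22.7%. Mean coverage was 3.08% on the X and 12.7 ± 1.7% on autosomes. Within genes of the same length X-linked genes ranked at 37.5, and autosomal genes at 50.8 ± 2.8. The X ranked 20 of 20 in both measures. In replicate 1 alone 13.6% of X-linked genes were marked, which was still below every autosome (28.4% or more). Peak lists cannot tell less of the mark on the X from a lower power to call peaks there. The most covered X-linked genes were Flna, which encodes filamin A, at 55.7 ± 11.8%, Maged1 at 54.8 ± 17.1%, and the demethylase gene Kdm5c at 51.9 ± 3.7%. These 3 were chosen after their values were seen.

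**Figure D3:**
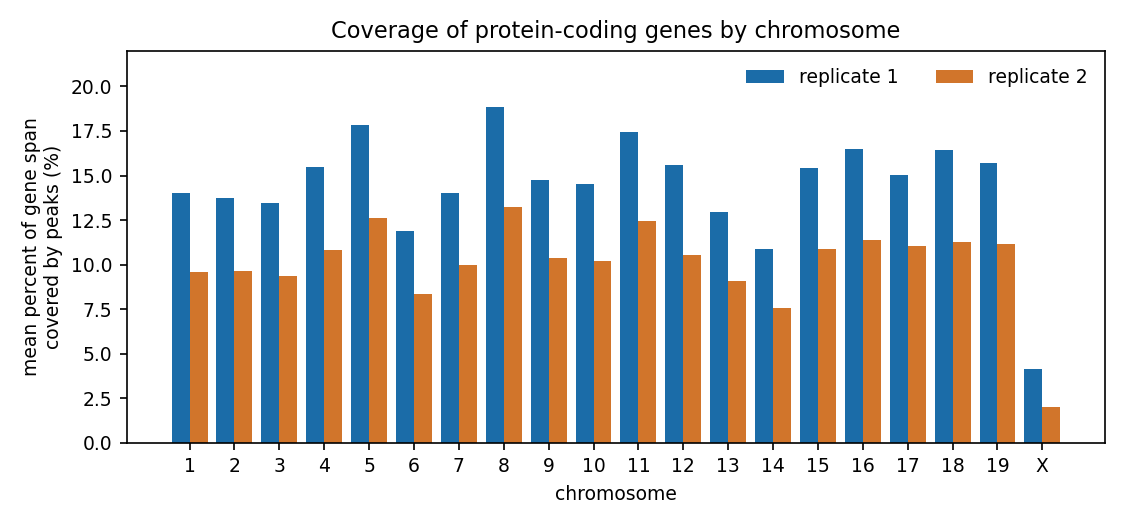
Mean percent of the gene span covered by peaks over the protein-coding genes of each chromosome (vertical axis), with 1 bar per replicate. The X chromosome stands at 4.13% in replicate 1 and 2.04% in replicate 2, below every autosome.

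The replicates ranked genes alike but at different levels. Across the 11137 genes with a peak base in either replicate, Pearson's r was 0.959 and Spearman's rho 0.952. These are across genes, which are not independent replicates, and no test was made. Marked genes were on average 44.3% covered in replicate 1 and 32.5% in replicate 2, a difference of 11.8 percentage points (SD 6.71 over genes), and 5886 of the 6074 (96.9%) were higher in replicate 1. Among genes of at least 20 kb the largest differences were in Ighmbp2 (71.6% and 39.3%), Bsdc1 (79.5% and 47.5%), Ppm1f (57.3% and 26.2%), Gpr89 (56.5% and 26.8%) and Dhcr24, a cholesterol synthesis enzyme gene (64.3% and 34.6%). In the opposite direction, again among genes of at least 20 kb, the proliferation marker gene Mki67 led with 14.5% in replicate 1 and 22.3% in replicate 2. It was followed by Manbal (10.8% and 14.2%), Zbtb25 (9.91% and 13.1%), Pdxk (1.76% and 4.91%) and Mocs1 (3.65% and 6.70%). Ighmbp2 and Gpr89 each overlap another protein-coding gene. With 1 peak list per pool these differences have no replicate check.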

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

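In this part the tests of the explanations for the difference between replicates, of a bounded loss of power on the X, of last exons in Zfp genes, and of how many peaks share the commonest fold for their p were chosen after the results were seen. The design has 1 group, so no biological difference between groups was tested, and of other biological explanations only different genes in the 2 pools and the gene content of the X were.

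Peaks outside the chromosomes of the report stood out as signal in data that no comparison used. Chromosome Y held 9 peaks in replicate 1 and 10 in replicate 2, of which 1 and 2 lay in Ddx3y, a Y-linked RNA helicase gene. Unplaced scaffolds held 88 peaks in replicate 1 and 19 in replicate 2, with a median authors' fold of 2.39 and 2.31 against 2.90 and 2.96 on the chromosomes analysed.

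Replicate 1 peaks covered 1.5 times as many bases as replicate 2 peaks. Of the 7491 genes marked in either replicate 1417 (18.9%) were marked in only 1 of them, 1370 in replicate 1 and 47 in replicate 2. Different genes carrying the mark in the 2 pools is argued against as the main reason, since these supplied 16.1% of the extra bases within genes and genes marked in both supplied 68.8%, and 125 of the 7491 (1.67%) held no peak base in the other replicate. In 51219 peak pairs that overlapped by at least 50% of both, the −log10 p of replicate 1 was a median of 1.36 times that of replicate 2, with a fold ratio of 1.03. This is consistent with a more sensitive peak call in replicate 1, through more reads or more control data. Which of these applies stays open, since the depth is unknown and the list of replicate 1 also drew on more source files, as does a difference between the pools in the level of the mark, which was not tested.

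Of the 100 highest peaks of the replicated list 52 lay in a Zfp gene, against 2.66% of peaks sampled evenly by rank. Reads shared between near-identical copies on the assembled chromosomes are argued against as the whole reason. In 164 marked Zfp genes, at least 95% of the sampled 32-base words of the highest peak occurred only once on these chromosomes. Their highest fold averaged 5.50 against 4.36 in other marked genes of the same length, a difference of 1.14 (two-sided permutation p = 2e-04, the smallest possible). Copies on unplaced scaffolds or absent from the assembly were not counted, so reads shared with those stay open. This test and those that follow compare means over marked Zfp genes, not the 100 highest peaks themselves. GC content is argued against in the same way, with a difference of 1.11 from marked genes of matched peak GC content (permutation p = 2e-04). The highest peak overlapped the last exon in 70.2% of marked Zfp genes and in 34.9% of others matched on last exon length, but highest peaks on long last exons are argued against as the whole reason, since a difference of 1.31 from marked genes alike in both remained (permutation p = 2e-04), and what else sets these genes apart stays open.

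On the X chromosome 6.50% of genes were marked. A different make-up of genes is argued against as the whole reason. Of 7 X-linked ribosomal, proteasome and complex I genes (Rpl10, Rpl36a, Rpl39, Rps4x, Ndufa1, Ndufb11, Psmd10) none was marked, against 118 of 149 autosomal members (79.2%, two-sided Fisher's exact p = 3.24e-05). A loss of power as large as that between the replicates is argued against too, because the X share in replicate 1 (13.6%) was below that of every autosome in replicate 2 (23.1% or more). A larger loss, from a lower X copy number in pools of unknown sex ratio, cannot be told apart from less of the mark. The fold at matched −log10 p was 1.02 and 1.04 times the autosomal one in the 2 replicates, within the bound set beforehand to count against lower depth. However, among peaks of lower −log10 p, the only ones counted, most shared the commonest fold for their p to within a small margin. These were 86.2% of the autosomal and 93.6% of the X peaks counted. For them that measure barely carries local depth, so that bound was set aside. The X share was 13.6% in replicate 1 and 6.50% in replicate 2, where the autosomal means were 36.8% and 30.3%. In percentage points the 2 falls were of similar size, and only relative to the share in replicate 1 was that on the X larger. Whether X coverage lay nearer the limit of detection was not tested.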

How the results depend on the processing

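The alternative that also left out last exons was chosen after the data had been seen, and all others were planned. Of 316 recomputed values for 57 results, 280 were kept. Test results were kept if they held their direction and their side of the threshold, and other values if they stayed within the spread. Counts, ratios, the replicate correlation, the longest domain and the share of marked genes higher in replicate 1 were kept if they changed by at most 1.5-fold. Of 147 named genes, 143 stayed within the SD of the replicates with −log10 q of at least 2, 145 with equal numbers of peaks and 126 with the replicated list, where 16 lay above and 5 below. Means left with 1 replicate always stay within that SD and are not counted. The 3′ and exon differences and the neural against non-neural contrast kept their direction and side of the threshold under every setting run on each. The overlap of replicates and the genic share kept their side of the threshold too, but as percentages they could not change direction. Without first and last exons, exons were covered 22.3 percentage points more than introns, again with no matching for position along the gene. The X ranked last under every setting run, with 13.6% of its genes marked without replicate 2 and 6.50% without replicate 1. Every gene marked in both replicates was, by definition, marked in each alone. Unknown depth limits all statements on genes with little or no coverage. No paired analysis was possible because the replicates form a single group. The clustered protocadherins have no member that overlaps no other gene, so that setting gave no value for them. Unless the setting itself shows the cause, the cause was not tested.

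Thresholds moved values by construction. Of the replicate 1 peaks 57.9% lay under replicate 2 at an overlap of 1 base and 20.8% at 80%, and in the other direction 84.3% and 62.6%. Of the replicated peaks 97.1% lay under replicate 1 at an overlap of 1 base and 76.5% at 80%, and 82.7% and 31.8% under replicate 2. Promoters of 2 kb held 1.39% of covered bases. Marked genes numbered 3684 at 25% covered. Joining within 1 kb and 10 kb gave 34047 and 10534 domains, 35 and 897 of them of 50 kb or more, and at 10 kb the longest was 232.2 kb.

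List calls near the threshold were lost, as differences from random lists in percentage points. With −log10 q of at least 2 these were the cell cycle (8.38), pan-neuronal (6.52) and oligodendrocyte lists (−8.11). With equal numbers of peaks they were 9.68, 6.96 and −8.90. Leaving out each replicate gave 8.77 to 12.5 for the cell cycle, 6.16 to 8.32 for pan-neuronal, −10.9 to −7.45 for oligodendrocyte and −0.767 to 0.418 for imprinted genes, and the first 3 lost their call without replicate 1. With the replicated list the pan-neuronal (7.53) and oligodendrocyte (−10.4) calls were lost. With genes that overlap no other the cell cycle (9.32) and pan-neuronal (6.24) calls were lost. With no length matching the pan-neuronal (3.73), oligodendrocyte (−7.50) and protocadherin (1.73) calls were lost, excitatory (−9.85) and mature synapse (−8.06) genes fell below random lists, and axon guidance turned to −7.35 with no call.

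Of the contrasts, excitatory against GABAergic genes lost its call (0.853 percentage points) when percent covered replaced the rank within genes of the same length, which changes the scale as well as the length adjustment. Oligodendrocyte against astrocyte genes, with no call anywhere, turned to 2.85 rank points with the replicated list and to 3.31 percentage points with percent covered and no length adjustment, and lay between −3.19 and 2.13 rank points on leaving out each replicate.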

Other observations

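The tests in this part, of coverage beyond gene ends and of splicing genes, were chosen after the data had been seen, and the genes and regions named here were chosen after their values were seen.

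Long non-coding genes clear of protein-coding genes carried little of the mark. Of 5110 such genes of at least 1 kb, 59 (1.15%) were marked in both replicates. Snhg17, a host gene of small nucleolar RNAs, had the highest coverage among those of at least 5 kb, at 61.1 ± 13.4% (SD, n = 2; chromosome 2, 158353700 to 158361580). The abundant nuclear RNA gene Malat1 had 37.9 ± 2.1% (chromosome 19, 5795690 to 5802672) and 2900076A07Rik 39.2 ± 11.5%. Tmem134 is also among them, at 42.7 ± 9.4%, since the annotation used gives it a non-coding type.

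Joining replicated peaks within 3 kb left 431 domains that touched no annotated gene of any type. The longest was 10.4 kb on chromosome 12 (108773127 to 108783574), 9.40 kb before the start of Yy1, a transcription factor gene, and it was 26.6% covered in replicate 1 and 20.9% in replicate 2. On chromosome 8 a domain of 7.94 kb (85622437 to 85630373) began 67.1 kb from Dnaja2 and ended 6.21 kb from Neto2. A domain of 6.46 kb near the start of chromosome 17 (3070002 to 3076459) was 95.7% covered in replicate 1 and 79.9% in replicate 2, with no protein-coding gene between it and that chromosome end. Whether reads in these gene-free domains are shared with near-identical sequence elsewhere was not tested.

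A hypothesis is that the mark follows transcription past annotated 3′ ends. In 1158 marked genes whose 5 kb flanks on both sides held no annotated gene, 15.9 ± 5.1% of the 5 kb after the end was covered, against 0.248 ± 0.13% of the 5 kb before the start (SD, n = 2). The difference averaged 15.5 percentage points over chromosomes (SD 3.06), in 20 of 20 (two-sided sign-flip permutation p = 1e-05, the smallest possible). Coverage went from 36.6 ± 10.3% in the first kilobase to 4.58 ± 1.9% in the last. In marked genes of at least 10 kb, the kilobase after the end had already shown 37.9 ± 9.7% and that before the start 1.02 ± 0.25%. The direction of the flank test was therefore known beforehand, and it gives no separate support to the hypothesis. Annotated ends that are too short would give the same picture and were not tested.

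A second hypothesis is that genes of the splicing machinery are covered above other genes as a class. It was drawn up after the top 10 genes by coverage among those of at least 20 kb had been seen. Of these, 6 were splicing genes or encode proteins that bind RNA. With those top 10 genes left out, the genes named as SF3, PRPF, SNRNP, SNRP, SRSF, HNRNP, U2AF or RBM averaged 40.3 ± 6.7% covered against 14.3% in random lists of the same gene lengths, a difference of 26.0 percentage points (two-sided permutation p = 2e-04, the smallest possible), and 84 were marked (83.2%) and 17 were not. This went with the hypothesis, but the difference was not particular to splicing genes. Ribosomal protein, proteasome and H3K36 methylation genes lay 27.3, 25.7 and 26.9 percentage points above their random lists. The other lists called above had smaller differences, the largest of them 15.7 in complex I genes. The splicing class was drawn up by gene symbol and the test ran on the data that prompted it.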
